A study of Mus musculus with 6 samples.

How the data were processed

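The signals are background-corrected Cy3 intensity values that the authors deposited as scanner output, made with Agilent Feature Extraction 9.5.3.1 per the file headers and 9.5 per the labels. A value table deposited for the series was identical to the processed signal of the scanner output, with medians of 88.3, 90.2 and 86.4 for Neo and 89.9, 85.4 and 50.2 for MR 4-25 in replicate order, so it was on the intensity scale, neither logged nor centred. Scanner images were not analysed here. Probe positions are those of the array's annotation, on build mm7, and no genome sequence was used here.

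Each array held 43379 gene spots and 1639 control spots. Control spots were left out, spots that the scanner software marked as outliers were masked, and the log2 signals of the spots of a probe were averaged, which left 41174 probes; 29 were dropped because all of their spots were masked on an array. The log2 of the array's 75th percentile over gene spots was subtracted from each value. Probes were kept when well above background on at least 3 of 6 arrays, which left 30965 probes. Names came from the RefSeq table through an accession for 22951 probes and a synonym for 3109; 6659 kept a name in the file that is a current symbol and 8455 a name that is not. The brightest probe stood for each gene, giving 21341 genes. Correlations between arrays across these genes, which are not independent replicates, were 0.888 to 0.984. They did not follow the lines alone. MR 4-25 3 correlated at 0.934 with Neo 3, above 0.891 and 0.904 with MR 4-25 1 and MR 4-25 2. Neo 2 correlated at 0.969 with MR 4-25 1, above 0.966 with Neo 1. The highest value was that of MR 4-25 1 with MR 4-25 2, and Neo 3 correlated best with Neo 2, at 0.941.

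Lines were compared with limma (3.58.1, R 4.3.3) by lmFit and eBayes, as MR 4-25 minus Neo, with Benjamini-Hochberg adjustment over the 21341 genes and an adjusted p of 0.05 as threshold. The 26 gene lists, each with at least 5 measured members, were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 26 lists, and again with the correlation estimated from the residuals and with fry. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. Tables were read with the R package data.table, version 1.17.8, and jsonlite 2.0.0, and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

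The comparison, its gene lists, the naming rule and the alternatives were chosen before the data were examined. Named genes were the 10 with the largest positive and the 10 with the largest negative log2 difference among genes with a current symbol that passed the test, did not overlap between lines and were well above background on all 6 arrays. To these were added, for each list, the 2 members of largest absolute difference past the test and the largest in the other direction. The rule also took, of genes with a current symbol detected in a single line, the 5 with the largest lower bound in each direction. With 13 fixed genes, this gave 64 genes. The exceptions are genes described as named after their values were seen, and a few genes of the rule are not reported here.

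Alternatives were normexp background correction with offset 50, quantile normalization, normexp with quantile, median scaling, no filter, a filter on all 6 arrays, the mean over probes, every probe on its own, the value table, an intensity trend with a robust fit, array quality weights, slide or replicate number as a block, slide 1 alone, and leaving out each array in turn. A pair of further alternatives, slide as a block with median scaling or with normexp and quantile, was added after the data were seen.

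Slides were read from the array identifiers in the file headers and were balanced between lines, so slide as a block changes the error of a difference and not its size. The labels give no pairing beyond the replicate numbers, so these were checked: across 21341 genes, the deviations of same-numbered arrays from their line's mean correlated at 0.29, 0.21 and 0.56, above the level of 0.1 set for treating the numbers as pairs, and the fit with a replicate block is given for that reason. In the 5079 brightest genes the same pairs correlated at 0.339, 0.0845 and 0.0974, so there only the pair numbered 1 was above that level. Over all 21341 genes crossed arrays of slide 1 also correlated, at 0.41 for Neo 1 with MR 4-25 2 and 0.38 for Neo 2 with MR 4-25 1, so the numbers and the slides are not separated by this check.

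In 10 simulations with the same design, 200 of 21341 genes were changed; the test found 4.48% of those changed 2-fold, 42.8% of those changed 4-fold and 64.5% of those changed 16-fold, and 6.75% of its calls were false. A simulated list of 40 genes shifted by 1 on the log2 scale passed camera in 10 of 10 simulations, and of 25 random lists in each, 1 passed in all. Simulated genes were drawn independently of each other and without a slide effect. These rates therefore do not cover genes that vary together, or a slide effect, in the measured arrays. The number of arrays limits the precision of every difference, and differences of dim probes are limited by what the signal holds over background.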

Results

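Gene expression was measured in 2 lines of S49, known as a mouse T lymphoma line that grows in suspension, on Agilent whole-genome arrays with a single dye, Cy3. The lines were Neo, the parental line, and MR 4-25, a line named for its recovery from mannitol, a sugar alcohol used to raise the osmolarity of culture medium. Each line had 3 samples, all labelled untreated, and 1 array per sample. Each array held 43379 spots for 41174 gene probes. On 5 arrays, 69.9% to 76.2% of these probes were well above background and the 75th percentile of the signal lay between 844 and 988 intensity units. The array of MR 4-25 replicate 3 was dimmer, with 61.3% of probes well above background and a 75th percentile of 521. Neo 1, Neo 2, MR 4-25 1 and MR 4-25 2 were on slide 1, and Neo 3 and MR 4-25 3 were on slide 2. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The comparison of MR 4-25 with Neo asks which genes differ in expression in the untreated line that had recovered from mannitol, in a series titled for hyperosmotic changes in lymphoid cells. With 1 recovered line and 1 parental line, the p-values do not cover how such lines vary among themselves. The recovery therefore cannot be told apart from any other difference between the 2 lines.

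In MR 4-25, Gzmb, a serine protease of cytotoxic granules, rose 650-fold over Neo, from a log2 signal of −3.32 ± 1.00 to 6.03 ± 0.95 relative to the array's 75th percentile (mean ± SD, n = 3 in each line). Ifng, the cytokine interferon gamma, rose 16.5-fold, from −4.00 ± 0.35 to 0.04 ± 0.82 (mean ± SD, n = 3), and 8 of 45 measured members of the interferon response list rose with it. Cd247, the zeta chain of the T cell receptor complex, fell 16.7-fold on its brightest probe, from −0.84 ± 0.17 to −4.90 ± 0.84 (mean ± SD, n = 3), and was 1 of 7 members of the T cell receptor list that fell. Among 17 measured genes of the osmotic stress response, 0 rose and 0 fell past the limma test, with 2 at an unadjusted p under 0.05. Over all genes 263 of 21341 passed, so a list of this size is too small to show a lack of calls.

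The 10 largest rises among genes well above background on all 6 arrays began with Gzmb, whose probe lies on chromosome 14 from 51126432 to 51126491 of mouse build mm7. Its log2 difference was 9.34 ± 0.70 (SE, n = 3 per line, limma adjusted p = 0.0118), with 9.39 on slide 1 and 9.25 on slide 2. Eras, a Ras-family GTPase of embryonic stem cells, rose 98.3-fold (adjusted p = 0.0114). S100a6, a calcium-binding protein, rose 77.3-fold, from −1.91 ± 0.13 to 4.36 ± 0.27 (mean ± SD, n = 3, adjusted p = 0.00265), with a difference of 6.09 on slide 1 and 6.63 on slide 2. Its probe lies on chromosome 3 from 90744440 to 90744499. Dcpp2 and Dcpp1, a pair of closely related secreted salivary proteins whose probes may detect each other's transcripts, rose 27.7-fold and 22.9-fold. Il22, a cytokine of T cells and innate lymphoid cells, rose 20.6-fold, Oaf rose by 4.32 on the log2 scale, and Plaur, the urokinase receptor, rose 18.3-fold. A2ml1, a protease inhibitor of the alpha-2-macroglobulin family, rose 17.3-fold, and Ifng was the tenth.

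Among the largest falls, Ptpn7, a tyrosine phosphatase of haematopoietic cells, fell 37.7-fold, with a log2 difference of −5.24 ± 0.22 (SE, n = 3 per line, limma adjusted p = 0.00407), −5.11 on slide 1 and −5.49 on slide 2; its probe lies on chromosome 1 from 135034314 to 135034373. Arsi, a sulfatase, fell 31.0-fold and Nt5dc2 fell 29.2-fold. Plac8 fell 28.7-fold, from 3.88 ± 0.06 to −0.96 ± 0.16 (mean ± SD, n = 3, adjusted p = 0.00265), with −4.81 on slide 1 and −4.91 on slide 2. Sdk1, an adhesion molecule, fell 19.1-fold, and Dock8, a guanine nucleotide exchange factor of lymphocytes, fell 17.6-fold on its brightest probe, while its other probes ranged from −4.32 to −0.00. Cd247 fell 16.7-fold, while its other probes differed by −1.18 and −8.88, the latter below background on all MR 4-25 arrays. Pdlim2 fell 15.2-fold, and Trat1, an adaptor bound to the receptor complex, fell 13.5-fold. The 10 rises and these falls passed the test with slide as a block. With the replicate number as a block, Gzmb alone among them passed (limma adjusted p = 0.0396). Within slide 1 alone, with 2 arrays of each line, Eras (adjusted p = 0.0707), Dcpp2 (0.0564), Ifng (0.139), Sdk1 (0.0797) and Trat1 (0.0674) did not pass.

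**Figure D1:**
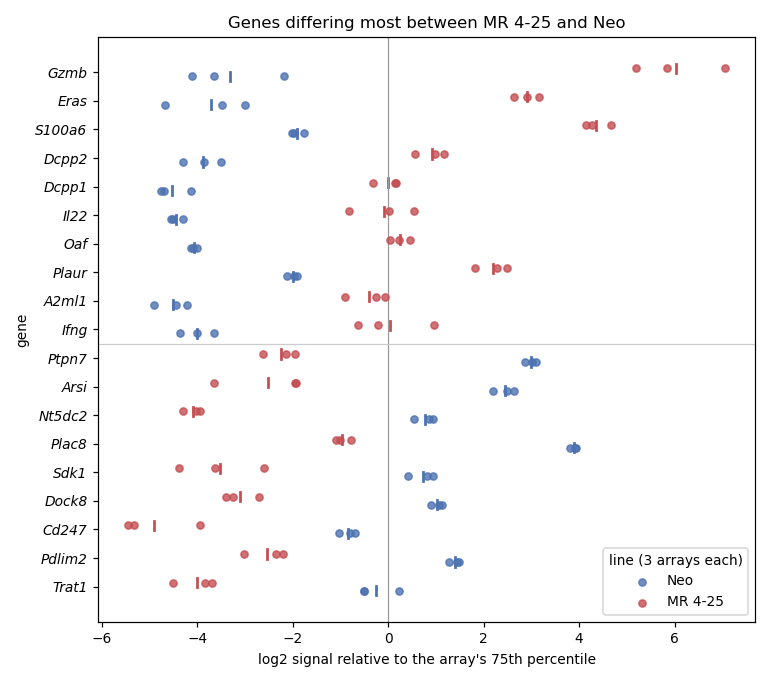
Log2 signal relative to each array's 75th percentile, with a dot for each of the 3 arrays of a line and a bar at the mean. Drawn are the 10 genes that rose most and 9 among those that fell most in MR 4-25. They were taken among genes with a current symbol that were well above background on all 6 arrays. Genes whose lines do not overlap were taken by rule, and Gzmb, at 6.03 in MR 4-25 and −3.32 in Neo on average, spans the widest gap.

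Genes of the T cell receptor complex and its signalling were lower as a group. Of 48 measured members, 7 fell, 0 rose and 41 did not pass the test; adjusted over the list alone, 21 fell and 1 rose. The median log2 difference was −0.39, with −0.36 on slide 1 and −0.64 on slide 2, and the list passed camera (adjusted p = 3.13e-09, against adjusted p = 0.0664 with an estimated correlation). The estimate for this list was 0.00652, below the preset 0.01, so a larger correlation among its members does not explain the higher p. Cd247 had a difference of −4.63 on slide 1 and −2.91 on slide 2, and Trat1 of −3.59 and −4.07. Regulators of T cell development did not pass camera as a list (adjusted p = 0.195, but 0.0462 with no filter), with a median of −0.22 over 46 members, −0.14 on slide 1 and −0.37 on slide 2. In that list 1 member rose, 1 fell and 44 did not pass, against 4 rising and 7 falling adjusted over the list alone. Il2ra, the alpha chain of the interleukin-2 receptor, rose from −2.19 ± 0.12 to 0.92 ± 0.23 (mean ± SD, n = 3, limma adjusted p = 0.00759). Tox, a nuclear factor of thymocyte development, fell 5.73-fold (adjusted p = 0.0483), a call that was lost with slide as a block (adjusted p = 0.0545). Of 40 genes of lymphocyte adhesion and trafficking, 0 rose, 2 fell and 38 did not pass, and adjusted over the list alone 2 rose and 2 fell. Their median was −0.18, with −0.12 on slide 1 and 0.14 on slide 2, and camera gave an adjusted p of 0.736. Itgal, the alpha chain of the integrin LFA-1, fell 4.69-fold (adjusted p = 0.0190), and Jaml, a junctional adhesion molecule of leukocytes, fell 2.83-fold (adjusted p = 0.0483).

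Interferon-responsive genes were higher in MR 4-25. Of 45 measured members, 8 rose, 0 fell and 37 did not pass; adjusted over the list alone, 16 rose and 1 fell. The median log2 difference was 0.54, with 0.41 on each slide, and the list passed camera (adjusted p = 9.43e-10, against adjusted p = 0.144 with an estimated correlation). Tgtp1, an interferon-inducible GTPase with close paralogs that its probe may also detect, rose 13.2-fold on its brightest probe (limma adjusted p = 0.0160). Its other probe differed by 0.76 ± 1.35 (SE) and did not pass (adjusted p = 0.855 over all probes). Ifi44 was well above background on the 3 MR 4-25 arrays and on 0 of the Neo arrays, and was at least 7.79-fold higher in MR 4-25 (adjusted p = 0.0274). Such a bound sets the line below background to the lowest signal that counts as well above background on each of its arrays, or to the gene's own signal where that is higher. Here and below, the p beside a bound comes from limma on the gene's own signals, those below background included. The bound itself was not tested. Named after their values were seen, Gbp3, Igtp, Gbp2 and Irgm2, GTPases induced by interferon gamma, rose by 2.92, 2.20, 2.08 and 1.67 on the log2 scale. Immediate early genes, which respond to handling of cells, and myeloid markers also passed camera upward in MR 4-25, with medians of 0.46 and 0.27, against adjusted p = 0.480 and adjusted p = 0.318 with an estimated correlation. The myeloid call was also lost with the replicate block and within slide 1 (adjusted p = 0.0511 and 0.103).

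In the list of MHC class I and antigen processing, 5 of 27 measured members rose, 2 fell and 20 did not pass, and adjusted over the list alone 11 rose and 6 fell. The median was 0.36, with 0.21 on slide 1 and 0.71 on slide 2. The list passed camera (adjusted p = 0.00983, against adjusted p = 0.318 with an estimated correlation), and did not with the replicate number as a block (adjusted p = 0.0511). H2-T23, a nonclassical class I molecule, rose from 3.31 ± 0.11 to 5.32 ± 0.19 (mean ± SD, n = 3, limma adjusted p = 0.0140). H2-T3, the thymus leukemia antigen, fell 7.80-fold (adjusted p = 0.0246). The brightest probe of H2-D1, a classical class I heavy chain, fell by 3.03 on the log2 scale (adjusted p = 0.0125), while its other probe rose by 3.55 (adjusted p = 0.0107 over all probes), so the array gives no single direction for this gene, whose relatives are similar in sequence. H2-Q2, H2-K1, H2-Q7 and Tap1, named after their values were seen, rose by 1.63, 1.49, 1.36 and 1.13; Tap1 encodes a subunit of the peptide transporter of antigen processing.

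Of 31 measured p53 targets and regulators, 2 rose, 0 fell and 29 did not pass, with the same 2 and 0 adjusted over the list alone. Their median was 0.28, with 0.30 on slide 1 and 0.21 on slide 2 (camera adjusted p = 0.00225, against adjusted p = 0.318 with an estimated correlation). Pmaip1, which encodes the pro-apoptotic protein Noxa, was well above background in MR 4-25 only and at least 14.0-fold higher there (limma adjusted p = 0.0272). Fas, the death receptor, rose 2.30-fold on its brightest probe (adjusted p = 0.0373), while its dimmer probe differed by −0.00. Of 22 death receptors and adaptors, 3 rose, 0 fell and 19 did not pass, and 4 rose adjusted over the list alone. Their median was 0.16, with 0.06 on slide 1 and 0.53 on slide 2 (camera adjusted p = 0.0198, against adjusted p = 0.318 with an estimated correlation), and the list did not pass with the replicate number as a block (adjusted p = 0.0532), within slide 1 (adjusted p = 0.1397) or without MR 4-25 replicate 3 (adjusted p = 0.148). Nor did it pass with no filter, a filter on all 6 arrays, the mean over probes or array quality weights (camera adjusted p = 0.0636, 0.173, 0.201 and 0.107). Traf1, an adaptor of tumour necrosis factor receptors, rose 4.21-fold (adjusted p = 0.0320). Tnfrsf9, the costimulatory receptor 4-1BB, rose 5.27-fold on its brightest probe (adjusted p = 0.04997), a call lost with slide as a block (adjusted p = 0.0561). Its other probe differed by 0.52 ± 1.25 (SE) and did not pass (limma adjusted p = 0.896 over all probes).

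Of 25 pro-apoptotic Bcl2 family members and caspase activators, Pmaip1 rose, 0 fell and 24 did not pass, and 1 rose adjusted over the list alone. Their median was −0.11 and their mean 0.09, and camera, which read the list downward, gave an adjusted p of 0.920. The medians on slides 1 and 2 were −0.05 and 0.11. Of 16 anti-apoptotic members, 0 rose, Naip2 fell 3.88-fold (limma adjusted p = 0.0209, with close paralogs) and 15 did not pass, and adjusted over the list alone 1 rose and 1 fell. Their median was 0.13 (0.06 and 0.14 on the slides), their mean −0.01, and camera read the list upward with an adjusted p of 0.415. Bcl2, Bcl2l1, Mcl1, Bcl2l11 and Trp53, the p53 gene, had log2 differences of 0.72, −0.13, 0.23, 0.25 and 0.49 on their brightest probes and did not pass the test. Another probe of Bcl2, well above background on all 6 arrays, rose by 2.34 (adjusted p = 0.0118 over all probes). In the cell cycle list Cdkn2a, a locus for inhibitors of cyclin-dependent kinases and of Mdm2, was well above background in MR 4-25 only and at least 18.3-fold higher there (adjusted p = 0.00265). It was the 1 of 47 members that rose, 0 fell and 46 did not pass, and adjusted over the list alone 3 rose and 1 fell. The list had a median of −0.09 (−0.11 and −0.03 on the slides), a mean of 0.07 and a downward camera adjusted p of 0.920.

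Genes of osmotic adaptation and ion transport gave 0 and 2 calls. Over all genes 263 of 21341 were called, so lists of this size are too small to show a lack of calls. Nfat5, the transcription factor of the osmotic stress response, had a log2 difference of 0.16 ± 0.20 (SE, n = 3 per line, limma adjusted p = 0.796). Its targets Slc5a3, Slc6a6 and Akr1b3, which take up inositol and taurine and make sorbitol, differed by −0.76, −0.10 and 0.01 and did not pass; the value of Slc5a3 was −0.00 on slide 1 and −2.28 on slide 2, where MR 4-25 3 alone was low. All 17 measured members of that list did not pass, 0 did adjusted over the list alone, and the median was 0.16 (0.10 and 0.21 on the slides, camera adjusted p = 0.163). Of 43 genes of cell volume and ion transport, 0 rose, 2 fell and 41 did not pass, and adjusted over the list alone 1 rose and 2 fell. Their median was −0.03 with all arrays, and 0.02 on slide 1 and 0.08 on slide 2, and camera read the list downward (adjusted p = 0.749). Kcna3, a voltage-gated potassium channel of T cells, was at least 4.11-fold lower in MR 4-25, where 0 arrays showed it well above background (adjusted p = 0.0499). Its call was lost with slide as a block (adjusted p = 0.0619), and with normexp its difference was 0.16 against a median shift of 0.34 over all genes. Aqp11, an aquaporin, fell 4.24-fold (adjusted p = 0.0256). Slc12a2, a cotransporter of sodium, potassium and chloride, differed by 0.82 and did not pass.

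Several stress and metabolic lists were higher with few single members past the test. Of 39 antioxidant and glutathione genes, 2 rose, 0 fell and 37 did not pass, with 5 rising adjusted over the list alone. The median was 0.34, with 0.17 on slide 1 and 0.55 on slide 2 (camera adjusted p = 0.000558, against adjusted p = 0.318 with an estimated correlation). Hmox1, heme oxygenase, rose 3.20-fold (limma adjusted p = 0.0404), and Slc7a11, the cystine transporter, rose 3.30-fold (adjusted p = 0.0490), which was lost with slide as a block (adjusted p = 0.0613). Slc7a11 was also the 1 of 37 members of the unfolded protein and amino acid starvation list that rose, with 0 falling, 36 not past the test, and 2 rising adjusted over the list alone. That list had a median of 0.23, with 0.18 and 0.26 on the slides (camera adjusted p = 0.00260, against adjusted p = 0.318 with an estimated correlation). Of 24 glycolysis genes, 0 rose, 0 fell and 24 did not pass, and 1 rose adjusted over the list alone. Their median was 0.14, with 0.11 and 0.34 on the slides (camera adjusted p = 0.0365, against adjusted p = 0.49998 with an estimated correlation). The glycolysis call was lost with slide as a block (adjusted p = 0.122), with the replicate block (adjusted p = 0.0958), within slide 1 (adjusted p = 0.103) and without any 1 of Neo 1, Neo 3, MR 4-25 1 or MR 4-25 2 (adjusted p = 0.0721, 0.102, 0.0639 and 0.112). It was lost too with quantile normalization, no filter, the mean over probes and normexp with quantile (camera adjusted p = 0.132, 0.138, 0.0773 and 0.0564). With normexp the antioxidant, p53, MHC class I and death receptor lists did not pass (adjusted p = 0.707, 0.211, 0.807 and 0.425), and camera read the unfolded protein and glycolysis lists downward (adjusted p = 0.832 and 0.827). Normexp also brought the T cell development, heat shock and cell cycle lists past camera downward (adjusted p = 0.0101, 0.00925 and 0.000333) and the NK and cytotoxic list upward (adjusted p = 0.0102), with all genes shifted by 0.34.

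The remaining functional lists did not pass camera. Of 24 glucocorticoid receptor targets, 0 passed the test and 1 rose adjusted over the list alone, with a median of 0.20 (0.16 and 0.38 on the slides, adjusted p = 0.0982, and 0.0261 without Neo replicate 1). Nr3c1, the glucocorticoid receptor itself, differed by −0.25. Of 41 genes of MAP kinase and stress kinase signalling, 0 rose, 40 did not pass, and Rasal3, a Ras GTPase-activating protein, fell 10.6-fold (limma adjusted p = 0.0118). Adjusted over the list alone 1 rose and 1 fell, and the median was −0.09 (−0.01 and −0.15 on the slides, adjusted p = 0.749). Of 35 heat shock and chaperone genes, 0 passed over all genes and 0 adjusted over the list alone; the median was −0.03 (−0.12 and 0.10 on the slides), the mean 0.06, and camera read the list downward (adjusted p = 0.920). Of 27 cholesterol genes 0 passed by either count, with a median of 0.12 (0.22 and −0.08 on the slides, adjusted p = 0.552, but 0.0177 within slide 1 and 0.00502 without MR 4-25 replicate 3). Of 11 ABC transporters linked to drug efflux 0 passed and 1 rose adjusted over the list alone, with a median of 0.19 (0.08 and 0.04 on the slides, adjusted p = 0.376).

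Markers of other cell types were mostly not past the test. Of 17 myeloid markers, 0 passed over all genes and 2 rose adjusted over the list alone, with a median of 0.27, 0.03 on slide 1 and 0.87 on slide 2 (camera adjusted p = 0.0324, against adjusted p = 0.318 with an estimated correlation). The myeloid call was lost with the replicate block (adjusted p = 0.0511), within slide 1 (adjusted p = 0.103), without Neo replicate 3 (adjusted p = 0.102) and without MR 4-25 replicate 1 (adjusted p = 0.0863). It was lost too with no filter, the mean over probes, the intensity trend and array quality weights (camera adjusted p = 0.0636, 0.134, 0.116 and 0.0915). The same held with normexp and quantile (camera adjusted p = 0.0564). Of 16 NK and cytotoxic markers, Gzmb rose, 0 fell and 15 did not pass, and 1 rose adjusted over the list alone (median 0.20, 0.13 and 0.46 on the slides, camera adjusted p = 0.175, but 0.0329 with the filter on all 6 arrays). Of 17 B cell markers, Pou2af1, a coactivator of octamer-binding factors, rose 2.94-fold (limma adjusted p = 0.0230), Blnk, an adaptor of the B cell receptor, fell 3.74-fold (adjusted p = 0.0408) and 15 did not pass. The same 1 rose and 1 fell adjusted over the list alone (median 0.20, 0.06 and 0.27 on the slides, camera adjusted p = 0.376). Of 17 fibroblast and stromal markers, Vim, the intermediate filament vimentin that lymphocytes also express, rose 2.35-fold (adjusted p = 0.0363), 0 fell and 16 did not pass, with 1 rising adjusted over the list alone (median 0.10, −0.05 and 0.44 on the slides, camera adjusted p = 0.301). Of 10 erythroid markers 0 passed by either count (median 0.14, −0.14 and 0.54 on the slides, camera adjusted p = 0.827).

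Of 22 immediate early genes, 2 rose, 0 fell and 20 did not pass, and 4 rose adjusted over the list alone. Jund, a subunit of the transcription factor AP-1, rose 3.76-fold (limma adjusted p = 0.0342), and Zfp36, a protein that destabilises cytokine messages, rose 3.62-fold (adjusted p = 0.0230). The median was 0.46, with 0.56 on slide 1 and 0.51 on slide 2 (camera adjusted p = 0.00983, against adjusted p = 0.480 with an estimated correlation), and the list did not pass without MR 4-25 replicate 1 (adjusted p = 0.186).

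**Figure D2:**
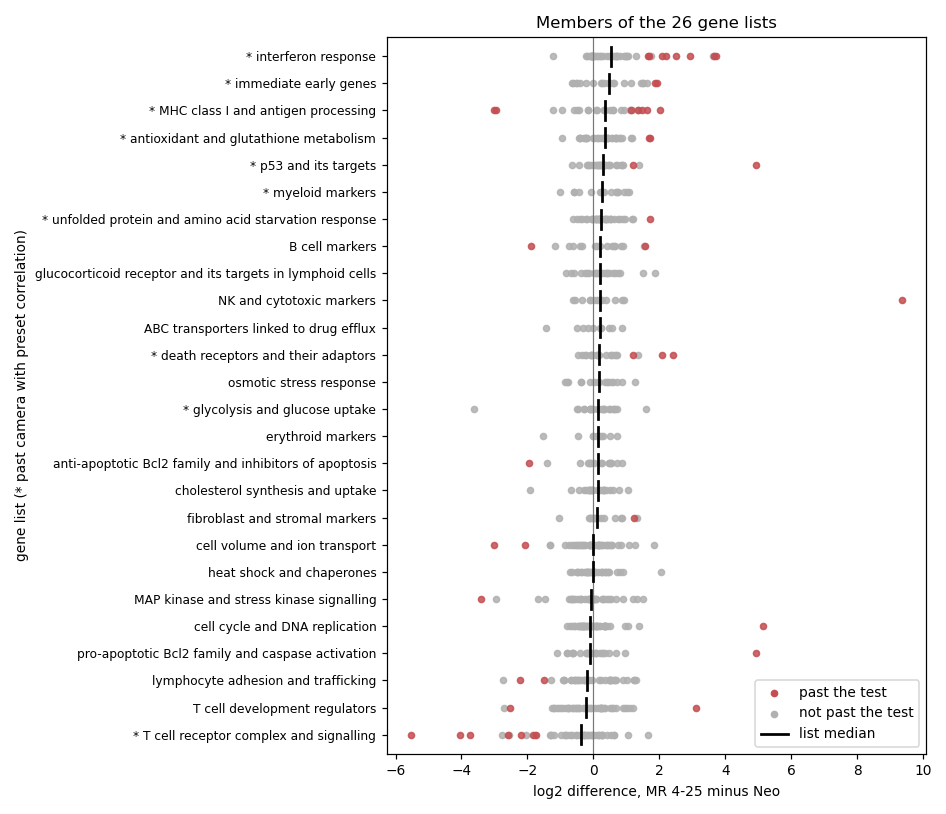
Log2 difference, MR 4-25 minus Neo, of each measured member of the 26 gene lists, with members past the test in red, the list's median as a black bar and an asterisk at the 10 lists past camera. The interferon list has its median at 0.54 and the T cell receptor list at −0.39.

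Well above background on every array of a line, and on 0 arrays of the other with any probe, were 15 genes in MR 4-25 and 70 in Neo. Of these, 8 and 21 have a current gene symbol, and 11 and 13 passed the limma test. The total of 85 genes was 56 with Agilent's positive and significant mark in place of well above background, and 363 when 2 of 3 arrays sufficed. The genes of MR 4-25 and of Neo numbered 15 and 226 without Neo 1, 16 and 115 without Neo 2, 40 and 85 without Neo 3, 18 and 282 without MR 4-25 1, 29 and 80 without MR 4-25 2, and 60 and 173 without MR 4-25 3. Among genes with a current symbol, the highest lower bounds in MR 4-25 included those of Cdkn2a, Pmaip1 and Ifi44. Beside them were Gja1, the gap junction protein connexin 43, at least 68.0-fold higher (limma adjusted p = 0.00697), and Fam50b, at least 8.08-fold (adjusted p = 0.0118). Of the genes with a current symbol, lower bounds led in Neo with Platr20, a noncoding RNA, at least 11.6-fold (limma adjusted p = 0.0208). Olfr299, one of many similar olfactory receptors, at least 5.59-fold (adjusted p = 0.0195), Enox1, at least 5.02-fold (adjusted p = 0.0181), and Kcna3 were also among the highest. With normexp, where the median difference over all genes was 0.34, Gja1 passed (3.39, adjusted p = 0.00701), while Cdkn2a (2.16, adjusted p = 0.123), Pmaip1 (1.91, 0.297), Ifi44 (1.69, 0.444) and Fam50b (1.60, 0.518) did not. On the Neo side Platr20 (−0.65, adjusted p = 0.599), Olfr299 (−0.04, 0.972) and Enox1 (0.02, 0.987) did not pass with normexp either. Thsd7b was at least 4.54-fold higher in Neo on a probe that is not its brightest, and its brightest probe differed by −1.25 and did not pass (adjusted p = 0.0686).

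In all, limma with Benjamini-Hochberg adjustment called 263 of 21341 genes, 144 higher and 119 lower in MR 4-25, and each of the 263 differed at least 2-fold. The 3 replicates of the lines did not overlap for any of the 263, which held for 24.3% of all genes tested and by chance would hold for 10%. With 3 arrays of each line, passing the test all but requires such a gap, so for the 263 it is no separate check. For single genes an exact permutation test of 3 against 3 cannot give a p under 0.1. With slide as a block, which leaves each log2 difference as it is, 338 genes passed, 172 higher and 166 lower, 247 of them among the 263; of the 50 genes past the test that were named by the rule fixed before the data were examined, 46 were kept. Within slide 1, 124 genes passed, 61 higher and 63 lower, including 96 of the 263. Of the 124 genes called within slide 1, 97.6% had the same direction on slide 2, which has 1 array of each line and no test. Of the 263, 89 were measured by further probes, and in 11 of these, H2-D1 and Fas included, some further probe had the opposite sign.

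These counts rest on single arrays and on the treatment of replicates. With the replicate number as a block, 1 gene passed, Gzmb (limma adjusted p = 0.0396), although 2814 genes had an unadjusted p under 0.05 against 2830 without the block. Without Neo 1 or Neo 2, 0 genes passed limma (1687 and 2014 at an unadjusted p under 0.05), and without Neo 3, MR 4-25 1, MR 4-25 2 and MR 4-25 3 the counts were 36, 9, 6 and 223, of which 25, 4, 4 and 92 were higher and 11, 5, 2 and 131 lower. With normexp background correction 80 genes passed, 55 higher and 25 lower, or 68.8% higher against 54.8%. Of the 26 lists, 10 passed camera, 9 upward and 1 downward, 9 of them with slide as a block, 6 with the replicate block and 7 within slide 1. With an estimated correlation 0 lists passed, with 2 at an unadjusted p under 0.05, and 4 of the 10 passed fry, which tests whether a list's genes move one way without comparing them with other genes. Among the 10, the estimate was above the preset 0.01 except for the T cell receptor and myeloid lists (0.00652 and −0.00201). For these exceptions, a larger correlation does not explain the higher p.

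**Figure D3:**
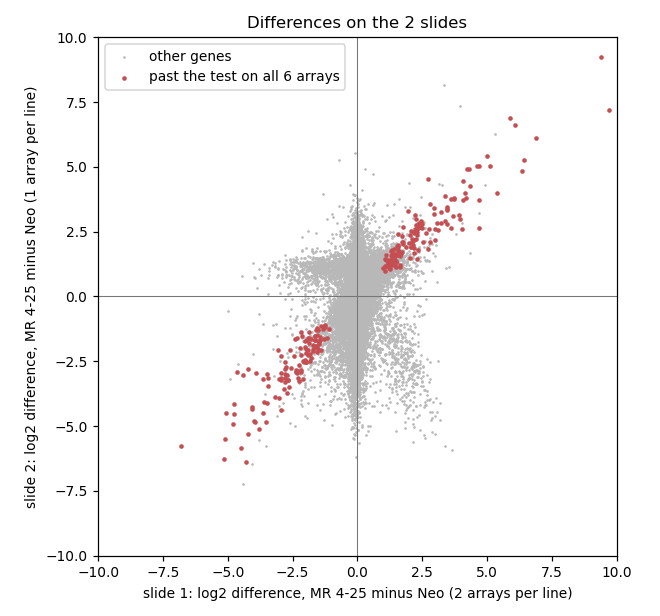
Log2 difference, MR 4-25 minus Neo, of each of 21341 genes on slide 1 (2 arrays of each line, horizontal axis) against slide 2 (1 array of each, vertical axis), with the 263 genes past the test in red. The 263 were called with the arrays of both slides, so their equal signs are no separate check; the correlation across all genes, which are not independent replicates, is 0.18.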

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

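The count of genes differing between MR 4-25 and Neo was 263, and 10 lists passed camera; genes higher in MR 4-25 were 144, genes lower in MR 4-25 were 119, and genes differing at least 2-fold were all of them. With normexp it was 80 (55 higher, 25 lower, 80 at least 2-fold), with a median difference of 0.34 over all genes, and 69 of the 263 calls were kept. With normexp and quantile the count was 504 (278 higher, 226 lower). With no filter, where the median difference over all genes was 0.10, 92 genes were higher. With a filter on all 6 arrays 524 genes passed (289 higher, 235 lower), and of every probe on its own 401 (186 lower, 401 at least 2-fold). An intensity trend with a robust fit gave 718 (367 higher, 351 lower, 405 at least 2-fold). Array quality weights, from 0.133 for MR 4-25 3 to 4.72 for MR 4-25 2, gave 2018 (942 higher, 1076 lower, 793 at least 2-fold). Within slide 1 the count was 124 (61 higher, 63 lower, 124 at least 2-fold). The replicate block left 1 gene (1 higher, 0 lower, 1 at least 2-fold) and 6 lists, and changed the call of 49 of the 64 named genes; this pairing changed no list beyond the 4 it lost. Leaving out each array in turn gave 0 to 223 genes (0 to 92 higher, 0 to 131 lower, 0 to 223 at least 2-fold). Slide as a block with normexp and quantile, added after the data were seen, gave 1111 (596 higher, 515 lower, 426 at least 2-fold). With an estimated correlation 0 lists passed, and with fry 4. Genes detected in one line and not the other numbered 85, 56 with the positive and significant mark, 363 with 2 of 3 arrays, and 109 to 300 with each array left out. For all of these changes the cause was not tested.

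Some directions reversed. With normexp the difference of Kcna3 was 0.16 and that of Enox1 0.0200, and the medians of the unfolded protein and glycolysis lists, 0.0667 and 0.0408, stayed below the 0.34 shift of all genes, so camera read them downward. H2-D1 had 3.58 with quantile normalization, where its other probe became the brightest, and 0.26 with the mean over probes of opposite sign. Of the 64 named genes, 62 kept their call with quantile normalization, 55 with median scaling, 59 with slide as a block and 37 with normexp. Quantile normalization, median scaling, the mean over probes, slide as a block and the value table gave 269, 196, 234, 338 and 263 genes. Signal over background limits what the array can measure for dim probes.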

Other observations

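Several genes outside the lists were named after their values were seen and were not tested as a group. Rhox5 and Esx1, homeobox genes of the X chromosome known from testis and placenta, rose in MR 4-25 by 2.43 (limma adjusted p = 0.0117) and 3.05 (adjusted p = 0.00697) on the log2 scale, beside Eras at 6.62. Grhl2, a transcription factor of epithelia, rose by 3.28 (adjusted p = 0.0122), Serpinb5 by 3.33 (adjusted p = 0.0491), Scel by 2.33 (adjusted p = 0.0181) and Pkp3, a desmosomal plakophilin, by 2.54 (adjusted p = 0.0283). Prdm1, a repressor that drives terminal differentiation of lymphocytes, rose by 2.60 (adjusted p = 0.0127).

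Other genes named after their values were seen were lower, and these too were not tested as a group. Gimap9, Lsp1 and Pstpip1 fell, with log2 differences of −2.79, −2.69 and −2.86 (limma adjusted p = 0.00759, 0.00924 and 0.00697). Pycard, the inflammasome adaptor, and Fermt3, an integrin activator, fell with differences of −3.50 and −2.43 (adjusted p = 0.00862 and 0.0267). Lair1, an inhibitory receptor, was at least 78.9-fold lower (adjusted p = 0.0153) and was well above background on 2 of 3 MR 4-25 arrays. Immp2l, a mitochondrial peptidase subunit, was at least 206-fold higher (adjusted p = 0.0163) and was well above background on 1 of 3 Neo arrays.

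The tests weighed for the rise of Gzmb, Ifng and interferon genes were chosen after the result was seen, although the fit within slide 1 that one of them uses was fixed before. NK or cytotoxic cells mixed into the MR 4-25 cultures could carry these genes, with other members of the NK list. The other 15 members had a median of 0.19, from −0.62 to 0.93, with 0 past the test, against 9.34 for Gzmb. Prf1, Nkg7 and Il2rb, dim in Neo yet well above background on all 6 arrays, differed by 0.65, 0.21 and −0.09. For these members, the sizes argue against such cells as the main source of Gzmb. With normexp the whole list, Gzmb included, had a median of 0.82 against 0.34 over all genes. It then passed camera upward (adjusted p = 0.0102), so the argument rests on the signals without normexp. Gzma and Tbx21, at 3.75 and 2.81 in Neo, were already bright there and could show little. Several others were below background on some arrays. Slides were balanced between the lines, so a slide effect alike in both lines cannot give the rise. A slide effect that differs between the lines, or the dim replicate 3 array, might. However, the interferon list had a median of 0.41 within slide 1 (camera adjusted p = 1.51e-09 there, against adjusted p = 0.144 with an estimated correlation on all arrays). Gzmb, Gbp3 and Tgtp1 also passed within slide 1 (limma adjusted p = 0.0264, 0.0421 and 0.0428), which argues against either as the whole cause. Ifng, Ifi44, Gbp2, Igtp and Irgm2 did not pass within slide 1 (limma adjusted p = 0.139, 0.126, 0.0713, 0.0596 and 0.111), with differences of 4.17, 3.61, 2.18, 2.05 and 1.53. A response of the cells to their own interferon gamma may play a part but stays open: the median of 12 interferon gamma genes, from −1.23 to 3.73, exceeded that of the other 33 members by 1.04, but these 12 were set after their values were seen and hold 5 of the 8 members that rose, so the difference cannot decide.

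All tests of the shift of chromosome 3 were chosen after the result was seen. Over 689 genes of chromosome 3 the median difference was 0.32, with 76.1% positive, and Gbp2, Gbp3 and S100a6 lie there. A slide effect is unlikely to explain it, since the median exceeded that of other genes by 0.23 within slide 1, and signal-dependent scaling is unlikely, since 0 of 10000 random lists matched on signal had a median as high (highest 0.12). A gain of chromosome 3 copies could give the shift, and 8 of 8 windows of 20 Mb had a positive median, from 0.21 to 0.37; no DNA was measured, so this is a hypothesis. The 708 genes of chromosome 10 had a median of −0.18, with 7 of 7 windows negative. Its genes past the limma test ran the other way, with 8 that rose and 2 that fell.

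Of the tests of the shared deviation of the replicate 3 arrays, that of dim spots was chosen after the result was seen and that of slide against culture round before. Deviations of Neo 3 and MR 4-25 3 correlated at 0.56 across all genes and at 0.0974 across the 5079 brightest, genes not being independent replicates, so it was weaker among the brightest. Noise that differs between arrays would not be shared, so this leaves open whether noise of dim spots has a part in it. A slide effect and a shared culture round may both apply, and 0 slide 2 arrays carry another replicate number than 3, so the data cannot tell them apart.

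The splits of the arrays into other groups of 3 and 3 were chosen before the result was seen. With 10 splits there are too few for a share under 0.05. The real split gave 263 genes and the highest other 180; 1 of 10 splits, the real one, had as many genes differing and 1 as many at least 2-fold apart. For genes in a single direction, 144 higher and 119 lower, 2 of 10 splits reached each count, since the other split placed all 180 in 1 direction. For lists past camera 1 of 10 splits reached the real 10, with 3 the highest other. The split with 180 genes set Neo 1, MR 4-25 1 and MR 4-25 2 against the rest and held the slide 2 arrays together. The 3 other splits that part all 3 replicate pairs gave 0 genes each.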
